A study of Caenorhabditis elegans with 6 samples.

How the data were processed

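Poly(A) RNA of A-class motor neurons was measured on 6 arrays of 1 colour, 3 from wild-type larvae and 3 from unc-37(e262) larvae of the L2 stage. Per the labels' protocols, animals were grown at 25 °C on 150 mm plates, and the RNA was amplified by 2 rounds of in vitro transcription and labelled with biotin. Such amplification favours the 3' ends of transcripts, and changes of level between arrays can be compressed or stretched by it. The tag was a FLAG-marked PAB-1 made under the unc-4 promoter, per the labels. A pull-down of tagged protein also brings down some RNA of other cells, so levels are those of an enriched sample and not of pure neurons. The labels call the arrays biological replicates, and do not say whether the 2 groups were grown or hybridised side by side. The array numbers in the labels are lower for every wild-type array (73 to 85) than for every unc-37 array (89 to 98); if they follow the order of processing, order and genotype cannot be told apart.

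The deposited values are probe set intensities on a linear scale, made with RMA, per the submitters' processing notes; the version of RMA, the probe set definitions and the scanner settings are not given in the sources used here. RMA subtracts background, sets the arrays to one distribution by quantile normalization and summarises the probes of a set on the log scale. That the scale is linear was read from the values, whose highest per array lay between 12124 and 15148 and whose medians lay between 50.1 and 52.4, since RMA values on the log2 scale would be far smaller. They were log2 transformed, as had been foreseen for that case. No array was normalized again for the main results, and no probe set was filtered out. There were 22548 probe sets. By the platform's gene table, 20766 named 1 gene, 887 named several and 895 none, and no gene was named from the last 2 kinds; of the 20766, 65 had a gene missing from the RefSeq gene table of assembly WBcel235. Together they stood for 17118 genes, of which 10188 had a symbol. The files name no genome build, so that table served only for names and for which genes neighbour each other.

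Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 22548 probe sets and a call at an adjusted p below 0.05. A log2 change is unc-37 minus wild type, and its standard error (SE) is that of the moderated fit. A gene was represented by its brightest probe set over all arrays among those that name it alone. With 3 arrays against 3, an exact permutation test of a single gene cannot go below p = 0.1, and calls rest on the spread shared across probe sets. Tested on simulated data for this comparison, with 200 of 22548 probe sets changed, the fit recovered 34.3% of those changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, with 5 false calls among 153. The simulated errors were independent between probe sets and arrays, with spreads drawn from the prior fitted to these data. Fewer probe sets were changed than the 1447 called in the data, so the real rates can differ.

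Before the data were examined, 32 gene lists were fixed. They were tested with limma camera at a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the 32 lists, with camera at an estimated correlation and limma fry beside it. Intervals of medians are 95% bootstrap intervals over genes from 10000 draws. Genes are not independent replicates, so these intervals describe the lists in these arrays. Named in the text, by a rule fixed at the same time, are unc-37, unc-4 and pab-1; acr-5, del-1, glr-4, ceh-12, vab-7, mig-1, mom-5, lin-17, egl-20 and unc-8; the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p below 0.05 and arrays that do not overlap; and up to 2 members of smallest p per direction in each list, where members that were not called are named only in part. Other genes were chosen after their values were seen: unc-17, cha-1, cho-1, unc-25, unc-54, dpy-3, dpy-7, dpy-8, fbn-1, daf-19 and lin-29, and, to name the members of small counts, dsh-1, cwn-1, acr-14, unc-38, acr-12, acy-1, egl-8, goa-1, ins-17, his-4, phat-2, lys-7, grd-10, dpy-13 and dpy-4. The sets of molt and larval timing, heterochronic and pharyngeal cuticle genes and a sweep over symbol families of at least 10 genes were also added after. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

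The alternatives were a trend in the prior variance, array weights, a filter on dim probe sets (the median level, or 6 on the log2 scale), a second quantile normalization, centring on each array's median, the replicate number as a block, leaving out each array, an adjusted p below 0.1, a fold of at least 1.5, the mean of a gene's probe sets, camera at an estimated correlation and, added after the rise of neuronal genes was seen, scaling to 17 pan-neuronal genes. The tests on other splits used all 10 splits of the 6 arrays into 3 and 3.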

Results

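Messenger RNA of the A-class motor neurons of Caenorhabditis elegans (the DA and VA neurons of the ventral cord, which use acetylcholine and drive backward movement) was measured on 6 arrays of 1 colour. It came from larvae of the L2 stage grown at 25 °C. RNA was taken by mRNA tagging, in which chosen cells make PAB-1, a protein that binds poly(A) tails, with a FLAG tag by which it and its bound transcripts are pulled down; here the unc-4 promoter drove it. There were 3 arrays of the wild-type strain N2 and 3 of unc-37(e262) mutants, which the labels call biological replicates. unc-37 encodes a corepressor of the Groucho family that acts with the homeodomain protein UNC-4. The comparison asks which transcripts of these neurons differ when unc-37 is mutant. The median intensity of an array lay between 50.1 and 52.4 on the linear scale, and the number of arrays limits the precision. Across probe sets, log2 values of arrays correlated at r = 0.986 to 0.991 within wild type, 0.984 to 0.990 within unc-37 and 0.964 to 0.981 between the groups. The first principal component held 57.3% of the variance and set the 3 unc-37 arrays on one side and the 3 wild-type arrays on the other.

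In unc-37 arrays the 12 largest rises among named genes were those of lep-5 (a noncoding RNA of developmental timing, log2 change 2.95 ± 0.55 SE, n = 3 per group here and throughout), unc-4 itself (2.74 ± 0.31), nssp-12 (2.34 ± 0.16), rrn-3.56 (a ribosomal RNA, 2.19 ± 0.43), the neuropeptide genes nlp-15 (2.05 ± 0.11), nlp-21 (2.00 ± 0.22), flp-11 (2.00 ± 0.26) and flp-9 (1.92 ± 0.16), the globin gene glb-22 (1.80 ± 0.18), the purine synthesis gene atic-1 (1.80 ± 0.17), nlr-1 (1.73 ± 0.13) and the peptide receptor gene dmsr-7 (1.66 ± 0.18). The 12 largest falls were those of idpp-12 (-3.36 ± 0.33), the collagen genes col-104 (-3.12 ± 0.31), col-109 (-3.09 ± 0.26), col-97 (-2.95 ± 0.28), col-48 (-2.82 ± 0.40) and col-77 (-2.36 ± 0.25), the pharyngeal cuticle genes abu-15 (-2.85 ± 0.30) and abu-14 (-2.38 ± 0.22), dbd-20 (-2.54 ± 0.23), the hedgehog-related gene grd-14 (-2.43 ± 0.30), nspb-11 (-2.35 ± 0.25) and nspb-12 (-2.33 ± 0.21). Of these, rrn-3.56, idpp-12, abu-15, nspb-11 and nspb-12 each rest on 1 probe set, of a kind (_x_at) that can also bind related transcripts. Their changes may therefore not belong to those genes alone. Of 22548 probe sets, 1447 were called by limma at a Benjamini-Hochberg adjusted p below 0.05, 867 higher and 580 lower, and 4697 had an unadjusted p below 0.05. Of 17118 genes, each taken at its brightest probe set, 1156 changed: 675 rose and 481 fell, with a change of 2-fold or more in 152 and 164 of them. With a second quantile normalization 542 rose and 551 fell, so the excess of rises was not kept. In all 1447 called probe sets the arrays of the groups did not overlap, as held for 25.9% of all probe sets against 10% by chance. Among the called genes, 318 had another probe set, which was not called in 199 of them and of opposite sign in 52. Called in 1 of 2 probe sets were, among others, atic-1, nlr-1, mom-5, cam-1, ace-1, ceh-32, inx-1, inx-3, twk-5, vab-8, spp-1 and col-149. The gene ifc-2 was called in 1 of 3 and lad-2 in 1 of 5. The count of changed genes was 642 without wild-type replicate 1, 504 without wild-type replicate 2 and 522 without unc-37 replicate 1, the call of lep-5 ended without wild-type replicate 1 (adjusted p = 0.0626) and unc-37 replicate 1 (0.0739), and that of rrn-3.56 without wild-type replicates 1 and 2 and unc-37 replicates 2 and 3 (0.0598 to 0.0783). When arrays were scaled to the mean of 17 pan-neuronal genes, a setting chosen after the rise of neuronal genes was seen, every log2 change became 0.52 lower, so that any change between 0 and 0.52 turns sign by construction, and 227 genes were called higher and 14095 lower. As all genes move alike, this scaling leaves a list's change relative to other genes as it was, also where camera calls a list differently.

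**Figure D1:**
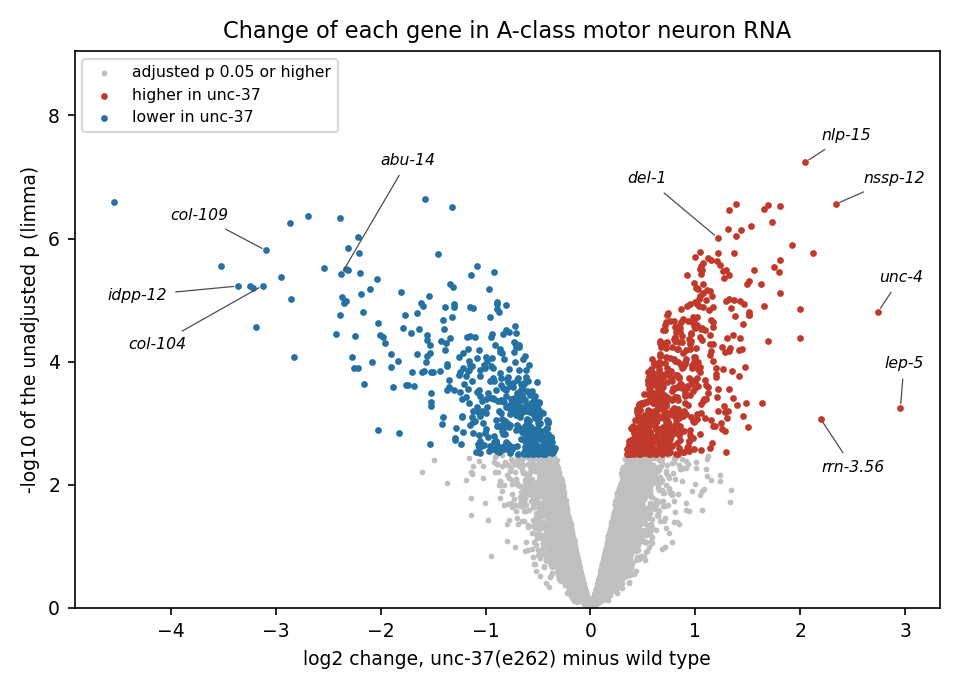
Each point is a gene at its brightest probe set: log2 change (unc-37 minus wild type, 3 arrays each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis, with the 675 called genes that were higher in red, the 481 lower in blue and the others in grey. The named falls, idpp-12 (-3.36), col-104, col-109 and abu-14, lie far left, and lep-5 (2.95) and unc-4 (2.74) far right.

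The unc-37 transcript was higher in unc-37 arrays, at 8.99 ± 0.10 (SD) against 8.49 ± 0.04 in wild type on the log2 scale, a log2 change of 0.50 ± 0.09 (adjusted p = 0.0159). Its other 2 probe sets changed by 0.29 (0.201) and 0.42 (0.157) and were not called. The labels do not say what e262 alters in the gene, so these levels do not test the labels. unc-4, whose promoter drove the tag, rose from 7.43 ± 0.69 to 10.17 ± 0.28, or 6.69-fold (adjusted p = 0.00245). The 3 probe sets of pab-1, the tagged coding sequence, gave changes of 0.17 to 0.35 and none was called (brightest: adjusted p = 0.365). The call of unc-37 ended with an intensity trend in the prior variance (adjusted p = 0.0522), without wild-type replicate 1 (0.0509) and without wild-type replicate 2 (0.0711), and with the arrays scaled to pan-neuronal genes its change was -0.02 and that of pab-1 -0.35.

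Genes of the B-class motor neurons, which drive forward movement, were examined because UNC-4 and UNC-37 are known to repress them in A-class neurons. Of 5 such genes, 4 rose: del-1, a sodium channel subunit (1.21 ± 0.10, adjusted p = 0.000996), glr-4, a glutamate receptor subunit (1.11 ± 0.12, 0.00209), ceh-12, a homeodomain gene related to HB9 (0.95 ± 0.13, 0.0045), and vab-7, a homeodomain gene related to even-skipped (0.78 ± 0.10, 0.00484). acr-5, an acetylcholine receptor subunit used as a B-class marker, was at 5.50 ± 0.04 in wild type and 5.51 ± 0.05 in unc-37, a change of 0.01 ± 0.08 (adjusted p = 0.979). The called gene vab-7 was also dim, at 4.73 in wild type and 5.51 in unc-37. A second probe set of glr-4 was called as well (0.64), and its remaining one was at -0.06. The same 4 were called when the p was adjusted over the list alone; the list comes from earlier work on UNC-4 and UNC-37, and whether that work drew on some of these arrays is not known here, so it is not independent evidence of its direction. The list passed limma camera at the preset correlation (median change 0.95, adjusted p = 4.8e-06), with adjusted p = 0.0608 with an estimated correlation.

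Wnt signalling was examined because earlier work placed Wnt receptors upstream of ceh-12 in these neurons. Of 31 Wnt pathway genes, 5 rose and none fell: the Frizzled receptors mig-1 (0.99 ± 0.16, adjusted p = 0.00993) and mom-5 (0.83 ± 0.14, 0.0113), the receptor tyrosine kinase cam-1 (0.59 ± 0.09, 0.00868), and dsh-1 and cwn-1. The dimmer probe set of mom-5 was at 0.29 and not called (adjusted p = 0.143). Adjusted over the list alone, 12 rose and 1 fell. The Frizzled gene lin-17 (0.53, adjusted p = 0.0847), the Wnt gene egl-20 (0.03, 0.891), the channel subunit gene unc-8 (0.28, 0.201), fixed with them, and the dishevelled gene dsh-2 (-0.43, 0.0918) were not called. The median change of the list was 0.20, below 0 once the 0.52 of the pan-neuronal scaling is taken off (camera adjusted p = 1.1e-04, and adjusted p = 0.101 with an estimated correlation). mom-5 was no longer called without wild-type replicate 2 (adjusted p = 0.0525), nor were dsh-1 and cwn-1 without wild-type replicates 1 and 2 or unc-37 replicates 1, 2 and 3 (0.0536 to 0.159).

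**Figure D2:**
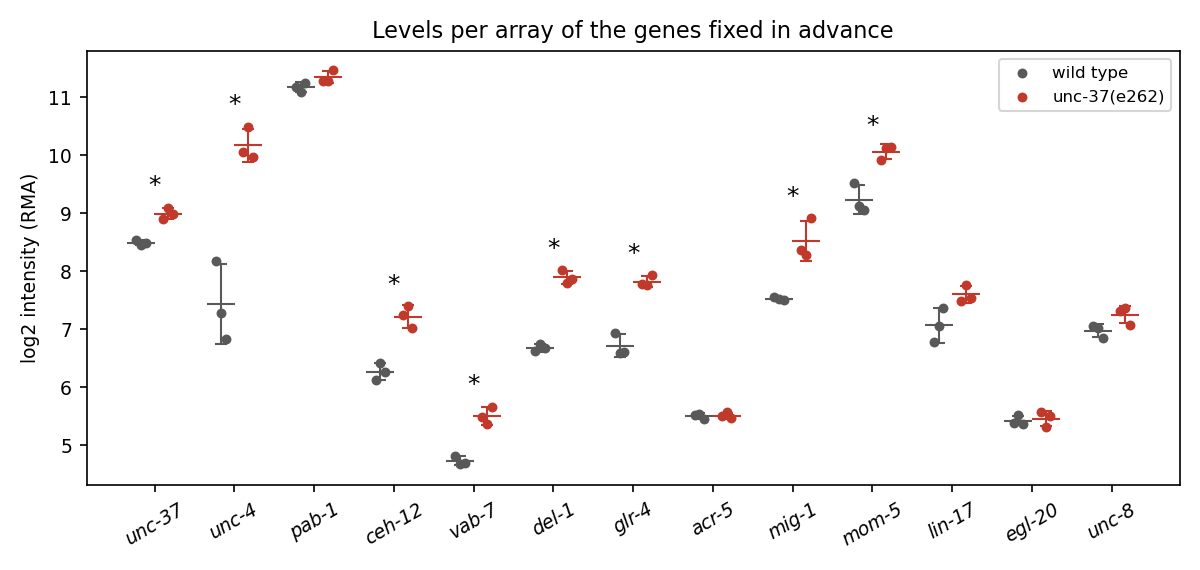
Log2 RMA intensity of 13 genes chosen before the data were examined (wild type grey, unc-37 red; points are arrays, horizontal lines means, bars ± SD, n = 3, and a star marks adjusted p below 0.05). unc-4 shows the widest gap, 7.43 against 10.17, while acr-5 sits at 5.50 and 5.51.

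Of 14 cholinergic and A-class genes, 10 rose and 1 fell: besides unc-4, the acetylcholine transporter gene unc-17 rose by 1.17 ± 0.14 (adjusted p = 0.00298), the choline acetyltransferase gene cha-1 by 1.32 ± 0.18 (0.00523), the choline transporter gene cho-1 by 0.98 ± 0.14 (0.00665) and the receptor subunit gene acr-2 by 1.05 ± 0.11 (0.00198). The acetylcholinesterase gene ace-1 fell by 0.70 (0.0161). unc-17, cha-1 and cho-1 were named after their values were seen. The same counts, 10 and 1, held adjusted over the list alone. The list had a median change of 0.84 (camera adjusted p = 1.3e-06, and adjusted p = 0.226 with an estimated correlation). The call of ace-1 ended without wild-type replicates 1 and 2 (adjusted p = 0.066 and 0.0648).

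Genes of synapses, and those that all neurons use, rose widely. Of 34 genes of the synaptic vesicle and active zone, 19 rose and none fell, 26 adjusted over the list alone, among them unc-13, a vesicle priming gene (1.02 ± 0.10, adjusted p = 0.00173), and the complexin gene cpx-1 (1.36 ± 0.17, 0.00386). Of 17 pan-neuronal genes, most of which are on that list too (together the lists hold 39 genes), 9 rose and none fell, 11 adjusted over the list alone, such as the vesicle genes rab-3 (0.90, 0.00667) and sng-1 (1.20, 0.00914). Of 58 genes of axon guidance and cell adhesion, 12 rose and 1 fell, 22 and 2 adjusted over the list alone, with the neurexin gene nrx-1 (1.15, 0.00135) and vab-8 (0.90, 0.00698) among the rises and lad-2 (-0.41, 0.0276) the fall. These are the 3 lists whose camera call held with an estimated correlation, each at adjusted p = 0.0435, and at the preset one at 5.4e-17, 9.5e-08 and 4.8e-06. Their medians were 0.65, 0.61 and 0.22, and the last is below 0 once the 0.52 of the pan-neuronal scaling is taken off. Of 21 genes of G protein and cAMP signalling, 5 rose and none fell, 6 adjusted over the list alone: gpb-2 (0.73, 0.0026), cnb-1 (0.69, 0.00914), acy-1, egl-8 and goa-1. Their median was 0.33, below 0 with that scaling (camera adjusted p = 8.3e-05, and adjusted p = 0.286 with an estimated correlation). Ribosomal RNA probe sets, which belong to none of these lists, rose in the same arrays, by 1.26 to 2.19, with 4 of 6 called. Their wild-type SDs were wide, at 0.72 to 1.08, and the cause of that rise was not tested. The calls of lad-2, acy-1, egl-8 and goa-1 each ended without wild-type replicate 1 or 2 or unc-37 replicate 1 or 2, and, except for acy-1, without unc-37 replicate 3 (adjusted p = 0.051 to 0.159).

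Ion channels changed in part. Of 65 potassium, calcium and sodium-leak channel genes, 16 rose and 1 fell, 18 and 1 adjusted over the list alone. The rises held the potassium channel gene egl-36 (1.05 ± 0.09, adjusted p = 0.00116) and unc-80, a part of the sodium-leak channel complex (1.27 ± 0.12, 0.0015), and the fall was twk-5 (-0.50, 0.0218). The median of this list was 0.03, below 0 with the pan-neuronal scaling (camera adjusted p = 0.00118, and adjusted p = 0.101 with an estimated correlation). Of 24 sodium channel genes of the DEG/ENaC family, 2 rose, del-1 and deg-1 (0.46, 0.0169), and none fell; del-3 was at -0.46 (0.0527). Adjusted over the list alone, 2 rose and 1 fell. Of 25 innexin genes, which form gap junctions, unc-9 (1.05, 0.00398) and inx-1 (0.56, 0.00913) rose and inx-3 (-0.83, 0.028) fell, 2 and 2 adjusted over the list alone. Neither family passed camera (adjusted p = 0.513 and 0.216). With single arrays left out, twk-5 was not called without wild-type replicates 1 and 2 and unc-37 replicates 1 and 2 (0.0627 to 0.0821), inx-3 without wild-type replicates 1 and 2 and unc-37 replicates 1 and 3 (0.0724 to 0.11), and deg-1 without wild-type replicate 2 and unc-37 replicate 1 (0.076 and 0.0699).

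Of 28 nicotinic receptor subunit genes, 5 rose, acr-2, acr-15 (1.45 ± 0.17, adjusted p = 0.00314), acr-14, unc-38 and acr-12, and eat-2, which acts in the pharynx, fell (-0.42, 0.0409). Adjusted over the list alone, 7 rose and 1 fell, and the list did not pass camera (0.0946), though it did, upward relative to other genes, without wild-type replicate 1 (0.0114). It also passed with the pan-neuronal scaling (0.00895), which moves every gene alike and so shows no rise relative to other genes. Of 20 glutamate receptor genes, glr-4 and glr-5 (1.02, 0.00927) rose and glc-1 fell (-0.85, 0.015), as they did adjusted over the list alone (camera 0.533). The directional test of limma fry gave adjusted p = 0.0133, though 40% of these genes lay above 0 and their median was -0.03. Of 89 homeodomain genes, 10 rose and 1 fell, 13 and 3 adjusted over the list alone (camera 0.472). Besides unc-4, ceh-12 and vab-7, the POU gene ceh-6 rose by 1.12 ± 0.10 (0.00129), and ceh-32 was the fall (-0.49, 0.031). Without single arrays the calls of acr-14, unc-38, acr-12, eat-2, glc-1 and ceh-32 each ended at least 3 times, always without wild-type replicate 2 and unc-37 replicate 1, at adjusted p = 0.0511 to 0.151.

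Genes of neuropeptides rose in part. Of 25 FMRFamide-like peptide genes, 6 rose and none fell, 9 and 1 adjusted over the list alone. They included flp-9, flp-11 and flp-18 (1.33 ± 0.15, adjusted p = 0.00229), and flp-1 was at -0.62 (0.0873). The median was 0.28, below 0 with the pan-neuronal scaling (camera adjusted p = 6.7e-04, and adjusted p = 0.286 with an estimated correlation). Of 58 other neuropeptide-like genes, 11 rose and 2 fell, 11 and 3 adjusted over the list alone. nlp-15 and nlp-21 lead the rises, and nlp-33, known for induction by infection in the epidermis (-0.92, 0.00985), and nlp-64 (-0.45, 0.0409) fell (camera 0.307). Camera passed the list upward with the pan-neuronal scaling (1.1e-04), which moves every gene alike and so shows no rise relative to other genes. Of 24 insulin-like genes, ins-4 (1.39, 0.0168), daf-28 (0.71, 0.0348) and ins-17 rose and none fell, also when adjusted over the list alone (camera 0.533). The calls of nlp-64, ins-4, daf-28 and ins-17 each ended without wild-type replicate 2 and unc-37 replicates 1 and 2, among others (adjusted p = 0.0531 to 0.16).

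Markers of other neurons mostly stayed without a call. Of 8 GABA neuron genes, the GABA transporter gene snf-11 rose (1.29 ± 0.24, adjusted p = 0.0195) and the other 7 were not called, such as unc-25, which makes GABA (0.12 ± 0.14, 0.709), and the homeodomain gene unc-30 (-0.23, 0.195). The same single call stood adjusted over the list alone. Of 10 touch receptor neuron genes, the tubulin genes mec-12 (1.66 ± 0.11, 0.000683) and mec-7 (0.96 ± 0.12, 0.0038) rose and none fell, 3 and none adjusted over the list alone. None of 25 ciliated sensory neuron genes and none of 9 monoamine and glutamate neuron genes was called by limma, nor adjusted over each list alone; 3 and 1 of them had an unadjusted p below 0.05, and a dimmer probe set of the ciliated gene daf-19 was called (0.52, 0.0157). These lists did not pass camera, at adjusted p = 0.733, 0.201, 0.513 and 0.854. The touch receptor list passed limma fry, at adjusted p = 0.0017 in its directional test and 1.3e-04 for either direction. Yet 50% of its genes lay above 0, with a median of 0.07. It passed camera with the pan-neuronal scaling (0.00622), which moves every gene alike and so shows no rise relative to other genes. snf-11 was no longer called without wild-type replicates 1 and 2 or unc-37 replicates 1 and 2 (0.0597 to 0.0822).

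Of 128 col genes, which encode collagens of the cuticle made by the hypodermis, 59 fell and 1 rose, 92 and 2 adjusted over the list alone. The falls included col-109 and col-91 (-2.21 ± 0.17, adjusted p = 0.000996), and col-149 rose (0.94, 0.0469). The median was -0.49 (camera adjusted p = 1.1e-32, and adjusted p = 0.101 with an estimated correlation). Of 43 other hypodermis and cuticle genes, 5 fell, grd-14, grd-5 (-1.88, 0.0112), grd-10, dpy-13 and dpy-4, and the hedgehog-related gene wrt-10 rose (1.64, 0.0158). Adjusted over the list alone, 9 fell and 4 rose, and the furrow collagen gene dpy-2 was at 0.82 (0.0527), with its other probe set called (0.81, 0.0308). Their median was -0.19 (camera adjusted p = 0.0162, and adjusted p = 0.602 with an estimated correlation), and camera turned upward with the pan-neuronal scaling (0.534). Camera no longer called that list with array weights (0.0685) or without wild-type replicate 2 (0.115) or unc-37 replicate 2 (0.0857). The calls of col-149, grd-10, dpy-13, dpy-4 and wrt-10 each ended without wild-type replicates 1 and 2, among others (0.0511 to 0.158).

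Of 16 pharynx genes, phat-5 (-1.52 ± 0.23, adjusted p = 0.00813), phat-4 (-1.16 ± 0.21, 0.0159) and phat-2 fell and none rose, 6 and none adjusted over the list alone. The median was -0.33 (camera adjusted p = 9.7e-04, and adjusted p = 0.286 with an estimated correlation). Of 27 intestine genes, the lysozyme genes lys-1 (-0.82, 0.0247) and lys-7 and the filament gene ifc-2 (-0.56, 0.0195) fell and spp-1 (0.66, 0.0157) rose, as they did adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.0294, and adjusted p = 0.57 with an estimated correlation). None of 29 body muscle genes was called by limma, nor adjusted over the list alone, and 2 had an unadjusted p below 0.05, with the heavy chain myosin gene unc-54 at 0.14 ± 0.21 (0.775) and unc-89 at -0.30 ± 0.12 (0.189). Of the 4 dimmer probe sets of unc-89, 1 was called (-0.49, 0.0409). The muscle median was 0.03, below 0 with the pan-neuronal scaling (camera 0.799). Camera no longer called the intestine list with array weights (0.0807), with the pan-neuronal scaling (0.484) or without wild-type replicate 2 (0.0682) or 3 (0.0505) or unc-37 replicate 3 (0.214), nor the pharynx list with that scaling (0.21). The call of phat-2 ended without wild-type replicate 1 or unc-37 replicate 2, and those of lys-1, lys-7, ifc-2 and spp-1 without wild-type replicate 2 or unc-37 replicate 1, among others (0.0507 to 0.122).

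Among lists of general cell functions, 3 of 26 histone genes rose and none fell, his-62 (0.49, adjusted p = 0.042), his-68 (0.36, 0.0413) and his-4, 9 and none adjusted over the list alone. These probe sets can bind several near-identical histone transcripts. The median of the list was 0.23, below 0 with the pan-neuronal scaling, which also turned his-62 (-0.03) and his-68 (-0.16) (camera adjusted p = 4.8e-06, and adjusted p = 0.342 with an estimated correlation). No member of the lists of ribosomal proteins (62 genes), germline genes (26), heat shock and stress genes (15) and cell cycle and DNA replication genes (32) was called by limma or adjusted over each list alone, where 0, 3, 1 and 5 genes had an unadjusted p below 0.05, and camera gave adjusted p = 0.165, 0.472, 0.513 and 0.3. Of 1323 chemoreceptor genes 6 fell and none rose (1 fell adjusted over the list alone), with srlf-35 (-0.80, 0.00346) and srbc-63 (-0.60, 0.0122, or 0.0543 without wild-type replicate 1) leading, and of 259 nuclear hormone receptor genes nhr-155 rose (0.86, 0.0107) and none adjusted over the list alone (camera 0.165 and 0.472). Camera called the chemoreceptors downward with array weights (0.014), with the filter at the median level (182 of them left, 0.00496) or at 6 (94 left, 7.1e-04) and without wild-type replicate 3 (0.0195) or unc-37 replicate 3 (0.00201). It also did so with the pan-neuronal scaling (8.1e-04), which moves every gene alike and so shows no fall relative to other genes. It called the ribosomal proteins upward with array weights (0.0371), the second quantile normalization (0.0459) or without unc-37 replicate 3 (0.0257), and the cell cycle genes downward without wild-type replicate 1 (0.0493). In all, 14 of the 32 lists passed camera at the preset correlation, 10 upward and 4 downward, 3 passed with an estimated one and 13 passed limma fry, which left out the pharynx, intestine and hypodermis lists and took in the glutamate receptor and touch receptor lists. A split of the arrays that mixed the genotypes also passed 14 lists at the preset correlation, so camera p-values at that setting can overstate the evidence. The calls of the 3 histone genes ended without wild-type replicate 1, 2 or 3 or unc-37 replicate 1 or 3 (0.0516 to 0.143).

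**Figure D3:**
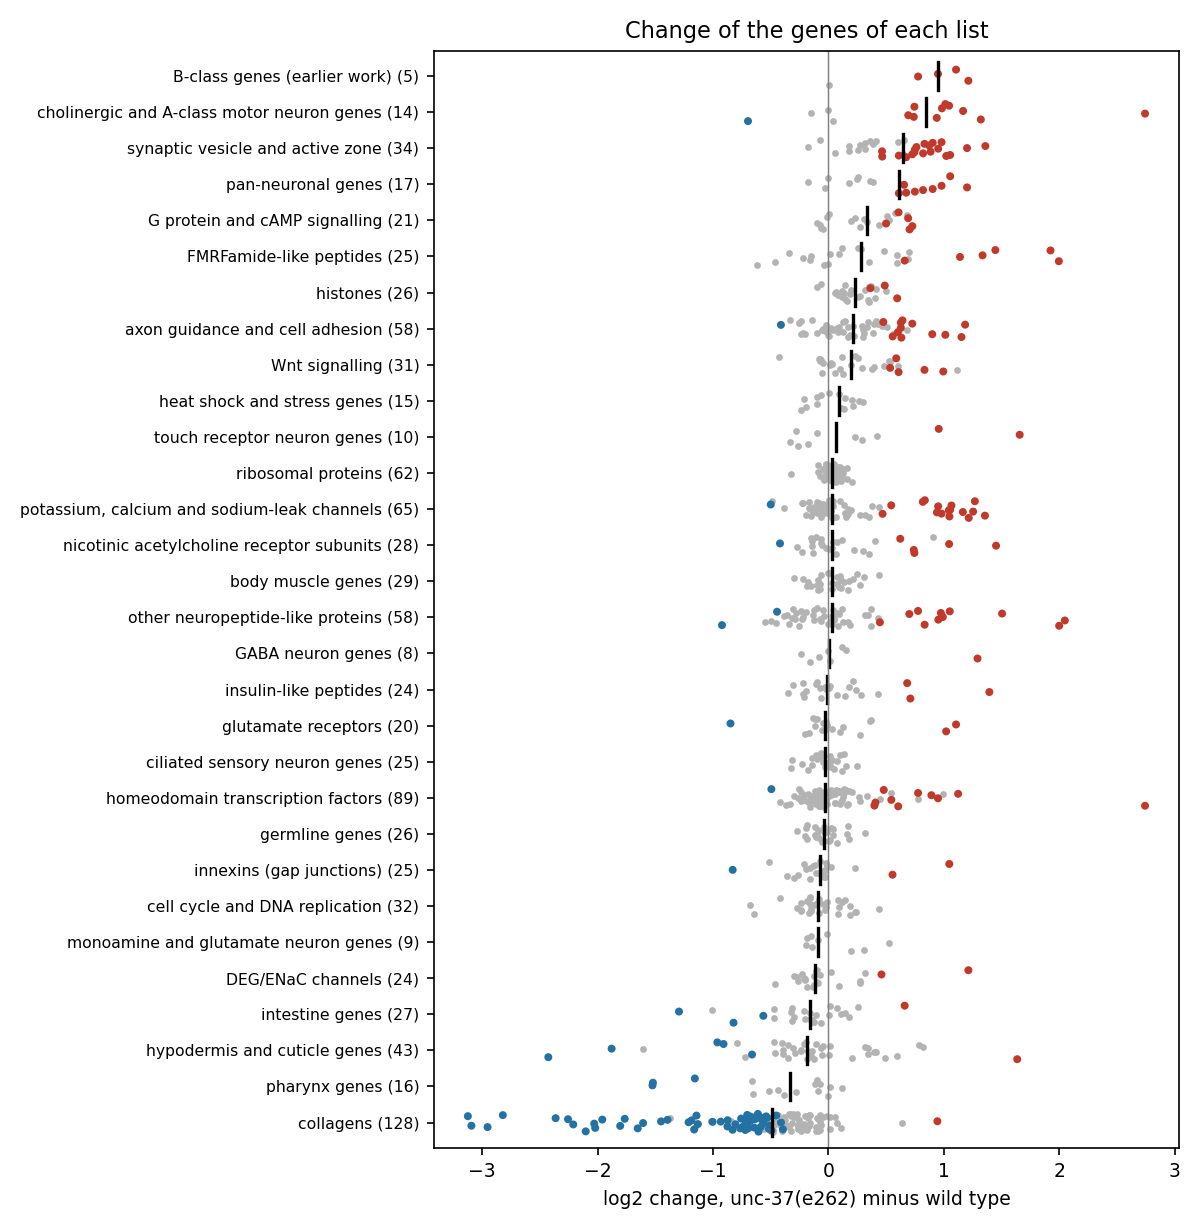
Each row is a list fixed before the data were examined, with its number of genes (the chemoreceptors and nuclear hormone receptors are left out), each point a gene's log2 change (red called higher, blue called lower, grey not called) and the black bar the median of the list. Collagens (median -0.49) lie lowest and the B-class genes (0.95) and cholinergic genes (0.84) highest, before any scaling to pan-neuronal genes.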

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

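The scaling to pan-neuronal genes was chosen after the result was seen; the other alternatives were fixed before the data were examined, and the cause of a change was not tested unless given. Changed probe sets (1447) and genes (1156) stayed within 1.5 times under the trend, both filters, the second quantile normalization, centring, the 1.5-fold threshold and the mean of probe sets. The balance of directions moved: 675 genes higher and 481 lower became 542 and 551 with the second quantile normalization (probe sets 727 and 665 against 867 and 580), 580 and 503 with the trend, and 765 and 427 with centring (977 and 515). Changed probe sets and genes numbered 2234 and 1766 with array weights, 2338 and 1863 at the looser adjusted p below 0.1, and 614 to 1677 and 504 to 1339 with 1 array left out, where fewer samples enter (785 and 642 without wild-type replicate 1, 614 and 504 without wild-type replicate 2, 650 and 522 without unc-37 replicate 1). Of the 97 called genes named in the text, 40 lost the call without at least 1 array. The rise of unc-4 and the calls of del-1, glr-4, ceh-12 and vab-7 held under every alternative read for single genes that kept their probe sets (the dim filters removed vab-7). The mean of a gene's probe sets was read for counts and lists only, and calls under the pan-neuronal scaling are weak, as most probe sets are called there. The trend ended the calls of ceh-32, eat-2, lad-2, nlp-64, his-62, his-68, dsh-1, cwn-1, egl-8 and ins-17, the second quantile normalization those of dpy-13, col-149, his-62, his-68, his-4, dsh-1, cwn-1, acr-12, goa-1 and ins-17, and centring that of grd-10. Calls were gained by dpy-2 and lin-29 with array weights, both filters and centring, by del-3 with the trend and array weights, and by lin-17 and flp-1 with array weights.

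The level of unc-37 (0.50, adjusted p = 0.0159) was no longer called with the trend (0.50, adjusted p = 0.0522) or the replicate block (0.50, 0.0588), and lay at 0.45 to 0.55 with 1 array left out. The replicate block gave 1065 probe sets and 867 genes; the numbers do not pair the arrays, since same-numbered arrays deviated at r = -0.19, -0.14 and -0.10 and no array's deviations correlated best with those of its own number.

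An estimated correlation left 3 lists of 14. With array weights camera lost the intestine and hypodermis lists (adjusted p = 0.0807 and 0.0685) and gained the ribosomal proteins and chemoreceptors (0.0371 and 0.014). Scaling to pan-neuronal genes takes 0.52 off every log2 change: 18765 probe sets (282 higher, 18483 lower) and 14322 genes were called, and these turned: unc-37 (-0.0222), pab-1 (-0.35), acr-5 (-0.52), daf-19 (-0.39), egl-20 (-0.49), unc-8 (-0.25), unc-25 (-0.40), deg-1 (-0.0623), egl-8 (-0.0226), unc-54 (-0.38), dpy-3 (-0.18), his-62 (-0.0338) and his-68 (-0.16). Calls of rises that ended with it were those of cam-1, inx-1, cnb-1, gpb-2, daf-28, spp-1, col-149, dsh-1, cwn-1, his-4, acr-14, unc-38, acr-12, acy-1, goa-1 and ins-17. The hypodermis list turned upward in camera, its median relative to all genes staying at -0.17, since the scaling moves every gene alike. Camera calls of lists gained or lost with that scaling thus show no change relative to other genes. acr-5 turned with array weights (-0.00489). With 1 array left out, uncalled values spanned 0 for acr-5 (-0.0219 to 0.0285), egl-20 (-0.0183 to 0.11), unc-25 (-0.00224 to 0.24) and unc-54 (-0.0351 to 0.39). Signal over background limits dim genes such as acr-5, near the median of all probe sets, and vab-7, at 4.73 in wild type and 5.51 in unc-37.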

Other observations

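The symbol families, the added gene sets, the furrow collagen set and the tests on the B-class genes and on unc-4 were chosen after the result was seen. The other tests here were written before their values were seen. The readings of the tests on unc-4, the B-class genes and the genes near unc-37 were made more cautious after their values were seen. Among 161 symbol families of at least 10 genes, 38 passed limma camera at the preset correlation, 20 upward and 18 downward, and none with an estimated correlation (lowest adjusted p = 0.509 with an estimated correlation). Receptors of neuropeptides were among the rises: 4 of 14 dmsr genes and 4 of 17 frpr genes rose and none fell, while of the 44 npr genes 3 rose and the family did not pass (median 0.03, camera adjusted p = 0.158). Of 30 globin (glb) genes 5 rose, and of 20 rab genes, which direct vesicle traffic, 5 rose. These family medians lay at 0.17, 0.17, 0.08 and 0.28. As the pan-neuronal scaling takes 0.52 off every gene, they turn below 0 by construction, which tests nothing about these families. Families of general cell functions passed upward as well, with few genes called: vps (2 of 32 rose, camera adjusted p = 2.5e-05), rpn of the proteasome (1 of 13, 10 adjusted over the family alone, 1.2e-04), the mitochondrial ribosomal mrpl (0 of 34 by limma and 8 higher at an unadjusted p below 0.05, 1.7e-04) and mrps (1 of 22, 0.00121), and dnj (2 of 29, 6.3e-04). Their medians of 0.26, 0.44, 0.23, 0.24 and 0.20 turn in the same way. Families of secreted proteins were among the falls: 17 of 220 C-type lectin (clec) genes, 7 of 33 astacin protease (nas) genes, 5 of 30 grl genes and 5 of 40 transthyretin-related (ttr) genes fell. Of 74 genes of the pharyngeal cuticle, 20 fell and 2 rose, with a median of -0.27 (adjusted p = 0.134 with an estimated correlation). Of 8 heterochronic genes, lep-5 was the only one called, and lin-29 (0.55, adjusted p = 0.0554) was higher with it adjusted over the list alone. The set passed camera upward (median 0.19, which that scaling turns, adjusted p = 0.0373) and limma fry (adjusted p = 0.0218), with adjusted p = 0.149 with an estimated correlation, and lep-5 lost its call without wild-type replicate 1 (0.0626) and unc-37 replicate 1 (0.0739).

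In the first pattern, 59 of 128 collagens fell, with a median of -0.49, and the pharynx and intestine lists had medians of -0.33 and -0.16 (camera adjusted p = 9.7e-04 and 0.0294, and adjusted p = 0.286 and 0.57 with an estimated correlation). A general loss of RNA from other cells would lower muscle and intestine as far, but the median of the 29 body muscle genes was 0.52 above that of the collagens (95% interval 0.39 to 0.66) and that of the intestine genes 0.33 above it (0.16 to 0.46), and the 11 muscle genes brighter than 10 on the log2 scale changed by -0.30 to 0.14 at their brightest probe sets (a dimmer one of unc-89 was called at -0.49), which argues against an equal loss from all other cells as the whole cause but leaves a loss from some of them open. A difference in larval or molt stage stays open: the 14 molt and larval timing genes had a median of 0.30, which a bound set in advance read as against it, but that bound was wrong because members moved both ways (4 higher and 3 lower adjusted over the list alone, with fbn-1 at 1.09; limma fry adjusted p = 0.554 for a shared direction and 0.0101 for either direction), and the rise of the heterochronic set does not settle it, as its camera call ended with an estimated correlation (adjusted p = 0.149). Less hypodermal RNA stays open too: the 4 furrow collagens dpy-2, dpy-3, dpy-7 and dpy-8 had changes above 0 (median 0.69, where dpy-3 alone turns under the pan-neuronal scaling), and a second probe set of dpy-2 was called (0.81, adjusted p = 0.0308), but limma fry over the 4 gave adjusted p = 0.191. An effect of unc-37 on cuticle genes in cells other than the tagged ones may also be at work and was not tested.

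In the second pattern, 4 of 5 B-class genes rose, which is what loss of repression by UNC-4 and UNC-37 in A-class neurons would give. A larger share of neuronal RNA in the unc-37 samples is a technical alternative, since pan-neuronal and synaptic genes rose as well. That rise was not shared by all neuronal lists. Medians were -0.03 for ciliated sensory, 0.003 for GABA, -0.09 for monoamine and glutamate and 0.07 for touch receptor neuron genes. These lists were dimmer in wild type, with median log2 levels of 5.83, 6.70, 6.25 and 6.25 in that order. Those of the pan-neuronal and synaptic lists were 7.93 and 7.94. As signal over background limits dim genes, the contrast decides little, and it does not test a larger share of the tagged neurons alone. The B-class median of 0.95 lay at percentile 98.3 of 10000 random sets of 5 from 39 pan-neuronal and synaptic genes (whose central 95% ran from 0.18 to 0.90), but its own interval was 0.01 to 1.21 and it exceeded the cholinergic median by 0.11 (-0.84 to 0.74). With arrays scaled to pan-neuronal genes, del-1 (0.69, adjusted p = 0.00102), glr-4 (0.58, 0.00136), ceh-12 (0.43, 0.0209) and vab-7 (0.25, 0.0497) were still called higher. The scaling calls most probe sets, so its adjusted p-values lie close to unadjusted ones. These 4 calls, that of vab-7 above all, are therefore weaker evidence than the same adjusted p in the main fit. The gene acr-5 was then called lower (-0.52, 0.00163), which is the scaling itself, as its unscaled change was 0.01. Loss of repression and a larger share of neuronal RNA cannot be told apart for this set, because it has 5 genes and the cholinergic genes rose about as far.

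In the third pattern, unc-4 rose by 2.74 (95% interval 2.04 to 3.45), which may reflect release of the gene from repression, though this was not tested. As the unc-4 promoter drove the tag, the amount of tag and the cells that made it may then differ between the groups. The rises of other genes may then not all lie within the same cells. The change of unc-4 exceeded the highest of 30 other cholinergic and pan-neuronal genes by 1.42. A larger share of tagged neurons stays open even so, because those 30 genes are used by other neurons too, whose RNA would dilute their rise, and no gene used by A-class neurons alone was on the lists. A higher dose of the transgene also stays open: the highest change among the 3 pab-1 probe sets was 0.35 (upper 95% bound 0.90), but pab-1 was brighter than 97.8% of genes in wild type, which would hide an added share.

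Of the 200 measured genes nearest to unc-37 on its chromosome, 21 were called, or 10.5% (95% exact binomial interval 6.62 to 15.6), against 6.56% of the 2469 genes measured there. The 95th percentile of windows of that size was 10.5%. A rule set in advance read a share at or below that percentile as against background variation linked to unc-37. The interval reaches above it, so the test decides nothing. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 1447 probe sets and 1156 genes, and the highest other split gave 0 of each, so 1 split of 10 reached the real count. For the lists, 2 splits reached the real count of 14, the highest other also giving 14. The other splits, which mix the genotypes, passed 1 to 14 lists while calling 0 genes. The count of lists passing camera at the preset correlation thus does not set the real grouping apart. With 10 splits the share cannot fall below 0.1, so the splits are too few for a share under 0.05.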
